A study of Mus musculus with 6 samples.

How the data were processed

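RNA of dissected CD1 mouse retinas was sequenced at 6 stages, from E12.5 to the newborn, with 1 library per stage. At least 6 retinas were pooled per library, 1 µg of total RNA with integrity numbers from 8.6 to 9.9 was used, and polyA RNA was made into strand-specific libraries by the dUTP method and read for 50 bases from one end, per the labels' protocols. The newborn library is labelled postnatal day 0 in its title and postnatal day 1 in its age, so it is called newborn, and its age was set at 1 day after E18.5 with 2 days as an alternative.

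The deposited table holds FPKM per gene symbol that the authors made with Cuffnorm. TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, Cufflinks 2.2.1, Cuffnorm and FastQC are named with the mouse builds GRCm38 and mm10, per the submitters' processing notes; the order of steps, the gene annotation, the scaling between libraries and whether counting used the strand are not given in the sources used here. The sums of the deposited FPKM differ between libraries, so the values are not scaled to equal totals. A table of FPKM holds no counts, and no count test was run. FPKM of rows shorter than a sequenced fragment, such as small nucleolar RNAs and microRNAs (209 of the tested rows), move in large jumps, and reads shared by close copies, such as the gamma crystallins, the alpha globins, Amd1 and Amd2, or pseudogenes, can be assigned to either. Values listed at 0 were kept as they are.

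Depth was estimated from the low values. For 2744 genes with a single annotated transcript of over 1000 bases, FPKM was multiplied by transcript length less an assumed mean fragment of 200 bases; the most frequent small value is what 1 read is worth, 0.0423 to 0.0463 in the FPKM's own scale. This is a depth after the authors' scaling, and approximate, since their transcript models are not known. Differences between libraries of about 10% lie within it.

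The values were taken as log2(FPKM + 1), and all slopes and differences are on that scale, which understates changes of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (13242 of 23284 symbols, 19241 of which were above 0 somewhere). A slope per day was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A second-order term of age was tested in the same way with an orthogonal polynomial and 3 residual degrees of freedom. The error of these tests is the scatter of single pooled libraries around a line or a parabola, in which stage, pool, dissection and library cannot be separated, and not a spread between animals. Differences between 2 libraries were counted at 2-fold with no test.

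Before the data were examined, 29 lists were fixed from textbook knowledge: cell cycle, retinal progenitor, late progenitor and Müller glia, neurogenic precursor, ganglion cell, amacrine and horizontal, cone, rod and general photoreceptor, bipolar, presynaptic, axon guidance, Notch, glycolysis, oxidative phosphorylation, mitophagy and autophagy, hypoxia response, apoptosis, ribosomal protein, stress and immediate early, lens, pigment epithelium, erythroid, endothelial and pericyte, microglia and macrophage, periocular mesenchyme, astrocyte and optic nerve, skeletal muscle, surface epithelium and control genes. Of 553 list entries, naming 542 distinct genes, 6 were not symbols of the table. Lists with at least 5 tested members entered limma's camera with a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. With an estimated correlation no list was called. Median differences of lists per step were placed among 10000 random lists of the same size matched on mean FPKM. A further 5 lists, given with the observations, were added later: late photoreceptor, late inner retina, early photoreceptor regulator, neighbouring tissue and further hypoxia target genes.

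Genes named in the text follow a rule fixed at the same time: the 12 steepest rising and 12 steepest falling genes past the threshold with a mean of at least 5 FPKM, changed the same way between the end libraries, without provisional symbols; up to 8 peaking and 8 dipping genes; the 3 largest increases and decreases per step; up to 4 called members per list by slope, or the 2 highest members of a list without a call; and 18 marker genes. Some genes that the rule names are not given here. Genes outside the rule were chosen after their values were seen: Lum, Pmel, Pgk1, Ldha, Vegfa, Gnat1, Sag, Atp6v0c, Gdf1, Lass1, Amd1, Amd2, Sncg, Islr2, Mapt, Eomes and those of the observations.

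Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of 5 FPKM, equal FPKM totals, quantile normalization, the newborn's age, stage order in place of days, eBayes without trend, and each library left out. The model was tested on simulated values for the 13242 genes: slopes of 0.1, 0.2 and 0.4 log2 per day were recovered for 25.4, 70.1 and 90.9% of 67, 67 and 66 altered genes with 9 false calls, and second-order terms of 0.5, 1 and 2 for 0, 41.8 and 69.7% with 1 false call. Coordinates are those of the GENCODE vM21 annotation of GRCm38, the same build, matched by symbol; 20911 of the 23284 symbols (89.8%) were found. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.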

Results

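Gene expression was measured by RNA sequencing in whole mouse retinas of the outbred CD1 strain at 6 stages of development: embryonic days E12.5, E13.5, E14.5, E15.5 and E18.5 and the newborn animal. Each stage was represented by 1 library made from at least 6 pooled retinas, so no stage had a replicate and no difference between 2 stages could be tested. The values were FPKM (fragments per kilobase of transcript, scaled for sequencing depth in a way not given in the sources used here) for 23284 gene symbols. The FPKM of a library summed to between 466360 at E18.5 and 585272 at E12.5, and 12588 to 13067 genes per library reached 1 FPKM. Read totals were not used here. The smallest steps between low values placed the scaled depth at about 21.6 to 23.6 M reads per library, so that 1 FPKM in a transcript of 2 kb rested on about 43 to 47 reads, a counting error of about 15%. Spearman correlations across genes were 0.966 between E12.5 and E13.5, 0.979 between E13.5 and E14.5 and 0.933 between E12.5 and the newborn, genes not being independent replicates.

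The series asks which genes change while the retina turns from a sheet of dividing progenitors into a layered neural tissue, and the trend with age was taken as its main comparison. Photoreceptor genes led the rise. Nr2e3, a nuclear receptor of rods (GRCm38 chromosome 9, 59942771 to 59960659, minus strand, protein-coding), rose by 0.94 ± 0.10 log2 per day (slope ± SE over 6 libraries), from 0.15 FPKM at E12.5 to 67.0 in the newborn. Nrl, the transcription factor that specifies rods (chromosome 14, 55518978 to 55524981, minus strand), rose by 0.86 ± 0.08 per day, from 0.14 to 62.0 FPKM. Opn1sw, the short-wave cone opsin (chromosome 6, 29376671 to 29388468, minus strand), reached 38.6 FPKM from 0.020, at 0.89 ± 0.10 per day. The cone transducin subunits Gngt2 and Gnb3 and the retinoid carrier Rbp3 rose by 0.82 ± 0.06, 0.82 ± 0.11 and 0.77 ± 0.10 per day. Some other single genes rose beside them. Fabp7, a fatty acid binding protein of radial glia (chromosome 10, 57784881 to 57788450, plus strand), climbed from 1.93 to 252.8 FPKM. The surface glycoprotein Thy1 rose from 0.029 to 32.3 FPKM, and the neuropeptide Npy from 0, as listed, to 25.03. BC048943 and the microRNA row Mir218-1 were also among the 12 steepest. Adjusted p values of the genes in this paragraph in limma ran from 0.0038 for Gngt2 to 0.017 for Mir218-1.

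Several steep falls were in single genes of early eye development, some of them lens genes. A fall within the retina could not be told apart from tissue carried along in the younger dissections. Sfrp2, a secreted Wnt modulator (chromosome 3, 83766321 to 83774316, plus strand), fell by 0.81 ± 0.10 log2 per day, from 1079 FPKM at E12.5 and 1417 at E13.5 to 39.8 in the newborn. Otx1, a homeobox gene, fell from 34.6 to 0.38 FPKM, and Stra6, a receptor for retinol binding protein, from 73.8 to 2.64. Wfdc1 fell from 100.8 to 1.62 FPKM. Foxe3, a transcription factor of the lens epithelium, and the lens connexin Gja3 fell from 103.8 and 44.1 FPKM to 0 as listed. The lens crystallin gene Cryaa did not pass (adjusted p = 0.087) and is given for comparison (chromosome 17, 31677807 to 31681733, plus strand); it stood at 7921, 2343, 2008, 6958, 1287 and 2.07 FPKM from E12.5 to the newborn. The protease Capn3 and the connexin Gja1 fell from 259.2 and 113.1 to 0.29 and 1.49 FPKM. Atp6v0c-ps2 fell from 166.4 to 0.15 FPKM while its parent gene Atp6v0c rose from 45.7 to 284.7, and reads of a pseudogene and its parent are easily exchanged. The short rows Snord57 and Snord1b, small nucleolar RNAs, fell to 0 as listed. Adjusted p values in limma of the genes that fell ran from 0.0028 for Stra6 to 0.046 for Snord1b.

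Of 13242 genes with a mean of at least 1 FPKM, 1496 rose and 1377 fell with age (limma, Benjamini-Hochberg adjusted p under 0.05, 4 residual degrees of freedom), which is 21.7% of those tested and 52.1% of the calls upward. With every library scaled to the same FPKM total, 3299 rose and 701 fell, 82.5% upward, and the median log2 difference of all genes between the newborn and E12.5 moved from 0.049 to 0.33. E12.5 has the largest total, so this scaling lowers its values. Its 100 highest rows hold 37.04% of that total, against 23.32% in the newborn, and the globin Hbb-y alone stood at 36823 FPKM. No gene passed without the newborn library, and without the E18.5, E13.5 or E14.5 library the counts were 202 and 177, 631 and 474, or 813 and 680. Without the E12.5 and E15.5 libraries together, a choice made after seeing the data, 1538 genes rose and 1410 fell, 1162 and 1008 of them shared with the full series.

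**Figure D1:**
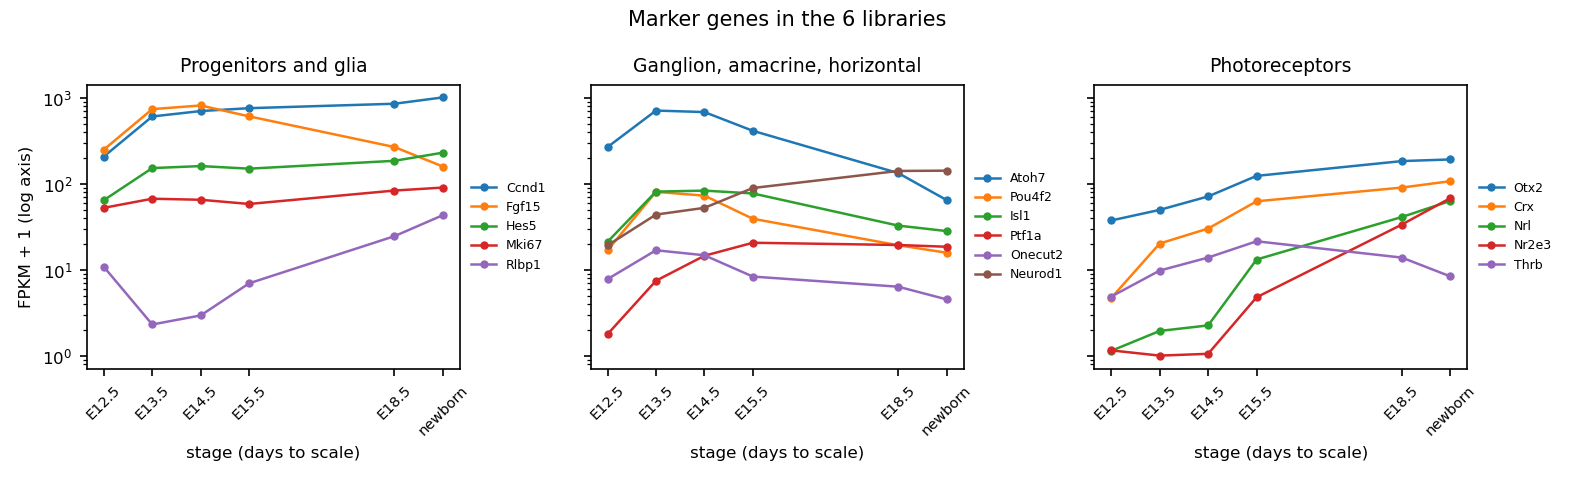
FPKM + 1 on a log axis against stage, days to scale, for marker genes chosen in advance, with 1 point per library and no error bars because each stage has 1 library. Nrl rises in every step, Nr2e3 climbs from E14.5 onward, and Atoh7 and Pou4f2 are highest at E13.5.

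Photoreceptor lists rose as groups. Of 19 measured rod and general photoreceptor genes 12 rose and none fell, 16 when adjusted over the list alone, among them the phosphoprotein Pdc (1.27 to 65.1 FPKM) and the chaperone Aipl1 (0.17 to 16.3 FPKM). Crx and Otx2, homeobox regulators of photoreceptor fate, rose by 0.54 ± 0.11 and 0.34 ± 0.04 log2 per day, to 105.8 and 190.3 FPKM. Of 10 measured cone genes 6 rose, 7 when adjusted over the list alone, including Gnat2 (0.37 to 13.2 FPKM), whereas the thyroid hormone receptor Thrb stood at 3.86 FPKM at E12.5, 20.4 at E15.5 and 7.34 in the newborn. Both lists rose against the other genes by camera (adjusted p = 2.5e-07 and 0.00016 with a preset correlation, 0.78 for both with an estimated correlation). At E15.5 several outer segment genes lay above both neighbouring libraries, among them the rod transducin Gnat1 with 53.6 FPKM against 0.59 at E14.5 and 4.53 at E18.5, and the arrestin Sag with 59.9 against 0.87 and 21.7. In the rod list 7 members were highest at E15.5 and 12 in the newborn, and 10 were higher and 9 lower at E18.5 than at E15.5.

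Synaptic genes and genes of inner retinal neurons rose as well. Of 22 presynaptic genes 11 rose, 15 when adjusted over the list alone, led by Snap25 (4.43 to 150.6 FPKM), Syp (4.97 to 86.0 FPKM), Rims1 and Cplx3. Of 18 amacrine and horizontal cell genes 9 rose, 13 when adjusted over the list alone (10 rising and 2 falling without E12.5), such as the calcium binding protein Calb2 (1.54 to 117.5 FPKM), the GABA synthesis enzyme Gad1 (0.030 to 19.3 FPKM), Lhx9 and the vesicular transporter Slc32a1. Ptf1a, which directs amacrine and horizontal fate, did not pass, with 0.77 FPKM at E12.5, 19.5 at E15.5 and 17.5 in the newborn, nor did Onecut2, highest at E13.5 with 15.8 FPKM. Of 10 bipolar cell genes 4 rose, with 6 adjusted over the list alone, including Lrit3, Lhx4 and Irx5. Trpm1, a channel of ON bipolar cells that pigment cells express too, fell from 122.4 to 1.53 FPKM. The lists rose in camera with adjusted p = 2.5e-07, 7.0e-05 and 0.047, and with an estimated correlation adjusted p was 0.78 for each. The bipolar call was lost under equal totals (adjusted p = 0.35), with the newborn set 2 days after E18.5 (0.053), with a pseudocount of 0.1 (0.051) and without a filter (0.086), and without the E12.5, E13.5, E14.5 or E18.5 library (0.14, 0.061, 0.072 and 0.059).

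Progenitor genes did not move in 1 direction. Of 20 retinal progenitor genes 2 rose and 4 fell, both over all genes and adjusted over the list alone; the fetal growth regulators Hmga2 and Lin28b fell from 63.2 to 7.35 and from 10.4 to 1.47 FPKM, and Id3 from 305.8 to 129.9 FPKM. Ccnd1, Fgf15 and Hes5 did not pass: Ccnd1 stood at 205.8 FPKM at E12.5 and 1006 in the newborn, and Fgf15 at 247.5, 810.6 and 157.2 at E12.5, E14.5 and in the newborn. Of 20 neurogenic precursor genes 9 rose and none fell, with 11 rising and 2 falling adjusted over the list alone; the proneural factors Neurod4 (2.78 to 98.4 FPKM) and Neurod1 and the Notch ligand Dll3 were among them. Atoh7, which ganglion cell fate requires (chromosome 10, 63099651 to 63101279, plus strand), did not pass, with 265.4, 707.2, 679.3, 410.7, 131.9 and 63.5 FPKM from E12.5 to the newborn. The precursor list rose in camera (adjusted p = 0.011, and 0.84 with an estimated correlation), but not without the E12.5 library (0.11, with 9 members rising and 4 falling) or under equal totals (0.22), and the progenitor list was not called (0.79). Of 17 late progenitor and Müller glia genes 6 rose and 1 fell, with 10 and 2 adjusted over the list alone; Sox8 went from 2.02 to 89.5 FPKM, Gpr37 from 1.43 to 41.6, Nfix from 2.53 to 14.01 and the potassium channel Kcnj10 from 0.050 to 5.25. Rlbp1, the retinoid carrier of Müller glia, stood at 9.79 FPKM at E12.5, 1.30 at E13.5 and 42.0 in the newborn and did not pass. From E12.5 to E13.5 the median difference of the list was -1.05 log2 (percentile 0 of random lists), with 9 members at least 2-fold lower and 1 at least 2-fold higher. The pigment epithelium list had a median difference of -2.56 log2 in the same step (percentile 0). A fall of these glial list members within the retina could thus not be told apart from tissue carried along at E12.5. This list missed the threshold (adjusted p = 0.062) and was called without the E12.5 library (0.00029, 11 members rising), under quantile normalization (0.029) and with a pseudocount of 5 (0.041).

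Ganglion cell genes were highest in the middle of the series. Of 21 measured members 1 rose, Thy1, also when adjusted over the list alone, and none fell; 9 had their highest FPKM at E15.5 and 6 at E14.5. Pou4f2, a ganglion cell transcription factor, stood at 15.8, 79.3, 71.6, 38.1, 18.2 and 14.7 FPKM, and Isl1 at 20.1, 79.8, 82.0, 76.0, 31.5 and 27.1. The list was not called (adjusted p = 0.29), and leaving out the youngest or the oldest library gave opposite directions: downward without E12.5 (0.013, 8 members falling) and upward without the newborn (0.027). Of 22 axon guidance genes 2 rose, Plxna2 and Ephb1, and 4 fell, Ntn1 and Slit2 the most, both over all genes and adjusted over the list alone (list adjusted p = 0.79); without E12.5 2 rose and 10 fell.

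Ribosomal protein genes fell together. Of 24 measured members 22 fell and none rose, 23 falling when adjusted over the list alone, at small slopes: Rps2 fell by 0.18 ± 0.03 log2 per day, from 1954 to 811.6 FPKM, and Rpl14, Rpl3 and Rpl18 by 0.15 ± 0.02, 0.14 ± 0.02 and 0.13 ± 0.02. The list median was -0.11 log2 per day (camera adjusted p = 4.4e-10, and 0.78 with an estimated correlation). With equal library totals 12 members fell, while the median relative to all genes was -0.10 against -0.11 and camera gave adjusted p = 1.8e-14. With quantile normalization 1 fell, the relative median was -0.01 and the list was no longer called (adjusted p = 0.099), and without E12.5 9 fell. Of 12 broadly expressed control genes Hprt rose and Rplp0, itself a ribosomal protein gene, fell, also adjusted over the list alone; the list was not called (adjusted p = 0.40).

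The cell cycle, Notch, metabolic and apoptosis lists were not called in the full series. Of 30 cell cycle genes E2f1, Ccna2 and Mki67 rose, the last by 0.10 ± 0.02 log2 per day to 89.1 FPKM, and Plk1 fell, none of them when adjusted over the list alone (list adjusted p = 0.70); under equal totals 9 rose and none fell, and without E12.5 none passed. Of 18 Notch pathway genes 7 rose, such as Hey2 and Heyl, and 2 fell, with Jag1 from 28.3 to 1.196 FPKM (8 and 3 adjusted over the list alone, 6 and 4 without E12.5, list adjusted p = 0.27). Of 22 glycolysis genes Eno2 and Hk1 rose and the lactate transporter Slc16a1 fell, the same counts when adjusted over the list alone (list adjusted p = 0.68). Of 17 hypoxia response genes Ndrg1 (6.62 to 133.3 FPKM), Mxi1 and Hif1a rose, 2 rising when adjusted over the list alone (list adjusted p = 0.16). No oxidative phosphorylation gene of 26 passed by either adjustment, Atp5b standing at 624.2 FPKM at E12.5 and 523.4 in the newborn (list adjusted p = 0.40, with a median relative to all genes of -0.01 log2 per day, and 0.01 under quantile normalization; 5 rose under equal totals and 2 under quantile normalization). Of 26 mitophagy and autophagy genes Pink1 rose and Gabarap fell, with 1 rising and none falling adjusted over the list alone (list adjusted p = 0.18, and 0.037 upward under equal totals, where 9 rose). Of 18 apoptosis genes Xiap rose and Bcl2, Trp53 and Bcl2l11 fell (1 and 5 adjusted over the list alone, list adjusted p = 0.30). Without the newborn library the glycolysis and hypoxia lists rose (adjusted p = 0.0014 and 4.0e-05) and the oxidative phosphorylation list fell (0.019).

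Markers of tissues around the retina were highest in the youngest library. All 13 measured periocular mesenchyme genes had their highest FPKM at E12.5, as had 11 of 12 microglia and macrophage genes, 10 of 12 pigment epithelium genes, 9 of 12 endothelial and pericyte genes, 7 of 8 erythroid genes, 7 of 8 surface epithelium genes and 6 of 7 skeletal muscle genes, against 24.7% of all genes. From E12.5 to E13.5 the small matrix protein Lum stood at 52.8 and 1.79 FPKM, the pigment gene Pmel at 196.6 and 10.3, and the keratin Krt18 at 35.3 and 3.36. The lens list differed: 15 of 18 members were highest at E15.5, and Cryga stood at 6500 FPKM there against 1.28 in the newborn. By trend, 1 mesenchyme gene (Fbln1) and 2 microglia genes (Lyz2, Csf1r) fell, no lens, erythroid, muscle or surface epithelium gene passed, and Rrh of the pigment list, Kdr of the endothelial list and Slc1a2 among 5 astrocyte and optic nerve genes rose, with the same counts adjusted over each list alone. Epcam of the surface epithelium list stood at 10.1 and 2.49 FPKM at E12.5 and in the newborn, and Actc1 and Tnni1 of muscle at 13.8 and 0.12 and at 6.81 and 9.06. Among 8 stress and immediate early genes Ier3 and Nr4a1 rose (2 rising and 1 falling adjusted over the list alone, list adjusted p = 0.81). The lens, microglia, erythroid and mesenchyme lists fell in camera (adjusted p = 0.0052, 0.0056, 0.011 and 0.014, and 0.84 for each with an estimated correlation); without E12.5 the last 3 were lost (0.11, 0.11 and 0.61), with no microglia gene falling, and without the newborn the lens list was (0.80). The mesenchyme call was also lost at a mean of 5 FPKM (0.076). The pigment epithelium, endothelial, surface epithelium, astrocyte and muscle lists were not called (adjusted p = 0.30, 0.30, 0.30, 0.81 and 0.45), although the first 3 fell under equal totals (0.014, 0.011 and 0.021) and the endothelial list without E13.5 (0.049).

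**Figure D2:**
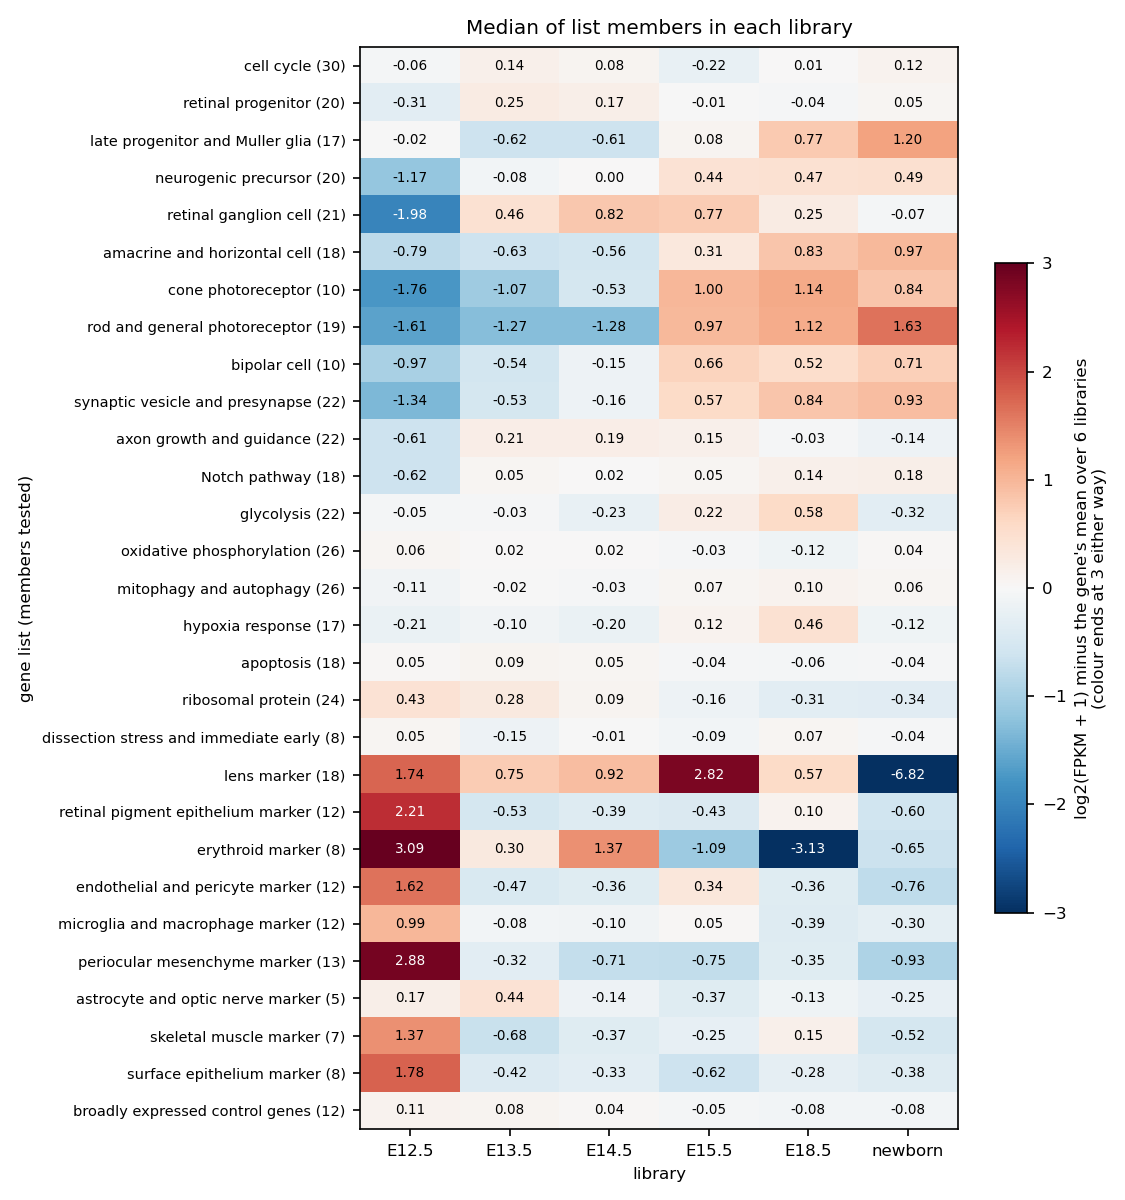
Median over the tested members of each of the 29 gene lists, in each library, of log2(FPKM + 1) minus the gene's own mean over the 6 libraries; colour and printed number give the same value, and the number of members stands in parentheses. Photoreceptor and synaptic lists go from negative to positive, ganglion cell genes are highest at E14.5 (0.82), tissue lists such as periocular mesenchyme (2.88) are highest at E12.5, and the lens list drops to -6.82 in the newborn.

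No gene was called as peaking or dipping within the series. The second-order term of age passed the adjusted threshold in limma for 0 of 13242 genes in either direction (3 residual degrees of freedom), while 1753 genes had a negative and 1025 a positive term at an unadjusted p under 0.05. The profiles of Atoh7, Pou4f2 and Fgf15 above therefore stand as values without a call. With a minimum mean of 5 FPKM 27 genes peaked and 3 dipped, and with equal library totals 23 peaked.

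Over the whole series 1376 genes were at least 2-fold higher and 1091 at least 2-fold lower in the newborn than in the E12.5 library on the log2(FPKM + 1) scale, a count without a replicate check. The median member of the rod list was 2.99 log2 higher in the newborn, of the cone list 2.47, of the presynaptic list 2.49 and of the amacrine and horizontal list 2.06, each above all but a few of 10000 random lists matched on expression (percentile 100). The median difference was 1.92 for ganglion cell genes, -7.84 for lens genes and -0.75 for ribosomal genes (percentiles 100, 0 and 0).

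The step from E12.5 to E13.5 held the most differences. At least 2-fold, 530 genes were higher and 605 lower at E13.5 than at E12.5, followed by 98 and 52 at E14.5, 338 and 103 at E15.5, 179 and 188 at E18.5 and 84 and 144 in the newborn, each against the library before and without a replicate check; the steps span 1 day each except E15.5 to E18.5 and, if the newborn was at postnatal day 1, the last. The median ganglion cell gene was 2.19 log2 higher at E13.5 than at E12.5 (percentile 100 of random lists), the median neurogenic precursor gene 1.12 and the median presynaptic gene 1.07 (percentile 100 each), while the mesenchyme, pigment epithelium and erythroid medians were -3.01, -2.56 and -2.69 (percentile 0 each). Retinal progenitor, axon guidance and Notch medians were higher too, by 0.56, 0.64 and 0.44 (percentile 100 each). The rod median was 0.11 (percentile 71.1), and the late progenitor and Müller median -1.05 (percentile 0). Less tissue carried along at E13.5 would also raise retinal genes relative to the rest, and this was not separated from changes within the retina. From E15.5 to E18.5 the ganglion cell median was -0.71 (percentile 0). Tissue lists moved both ways in that step, with medians of -2.34 for lens, -0.83 for erythroid, -0.77 for endothelial and 0.64 for pigment epithelium genes. Rod genes stood 2.55 higher at E15.5 than at E14.5, cone genes 1.34, late progenitor and Müller genes 0.84, amacrine and horizontal genes 0.80 and presynaptic genes 0.77 (percentile 100 each). In that step all 18 lens genes were at least 2-fold higher too, by 1.98 at the median, and all 12 endothelial genes were higher, by 0.70 (percentile 100 each). From E18.5 to the newborn, the median difference was -0.85 for glycolysis and -0.58 for hypoxia response genes (percentile 0 each), beside -7.41 for lens genes and 3.08 for erythroid genes (percentiles 0 and 100); Pgk1 stood at 683.5 and 322.3 FPKM, Ldha at 876.7 and 453.9, and Vegfa at 115.0 and 52.5. Cell cycle genes differed by -0.28 from E14.5 to E15.5 (percentile 0) and by 0.27 from E15.5 to E18.5 (percentile 100).

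Of the 30 places for genes with the largest step differences, 25 went to microRNA or small nucleolar RNA rows, whose FPKM jump with single reads because the features are short: Snord72 stood at 117.9, 0, 63.8, 0, 0 and 124.2. The other 5 were the embryonic globins Hbb-y and Hba-x, with log2 differences of -9.81 and -7.54 from E14.5 to E15.5, and the crystallins Cryga, Cryaa and Crygb, with -9.10, -8.71 and -8.57 from E18.5 to the newborn. With such rows left out, a choice made after the values were seen, the ganglion cell and axon genes Sncg, Islr2 and Mapt had the largest increases from E12.5 to E13.5. Sncg, a synuclein of ganglion cells (chromosome 14, 34370274 to 34374789, minus strand), stood at 23.5 and 276.7 FPKM, Islr2 at 11.5 and 113.2 and Mapt, the tau protein, at 2.99 and 35.2. At E14.5 the T-box gene Eomes stood at 8.61 FPKM against 0.61 at E13.5. Gnat1 and Sag were among the largest at E15.5, and BC048943, Nr2e3 and Opn1sw stood 2.91, 2.81 and 2.79 log2 higher at E18.5 than at E15.5, after Lass1. Lass1 shares its locus with Gdf1, and the pair moved in opposite ways: Lass1 stood at 9.93, 12.49, 0.10, 0.26, 9.41 and 0.32 FPKM and Gdf1 at 3.30, 3.11, 13.7, 14.4, 2.88 and 13.3, so values of both are uncertain. The same holds for Amd1 and its close copy Amd2.

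**Figure D3:**
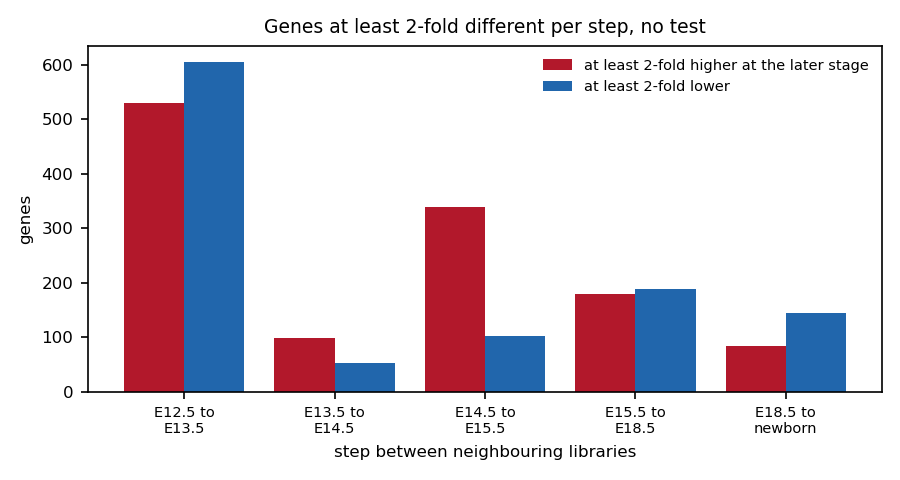
Number of genes at least 2-fold higher or lower at the later of 2 neighbouring stages on the log2(FPKM + 1) scale, among 13242 genes, with 1 library per stage and no test. The step from E12.5 to E13.5 holds 1135 genes and the step from E13.5 to E14.5 holds 150.

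**Figure D4:**
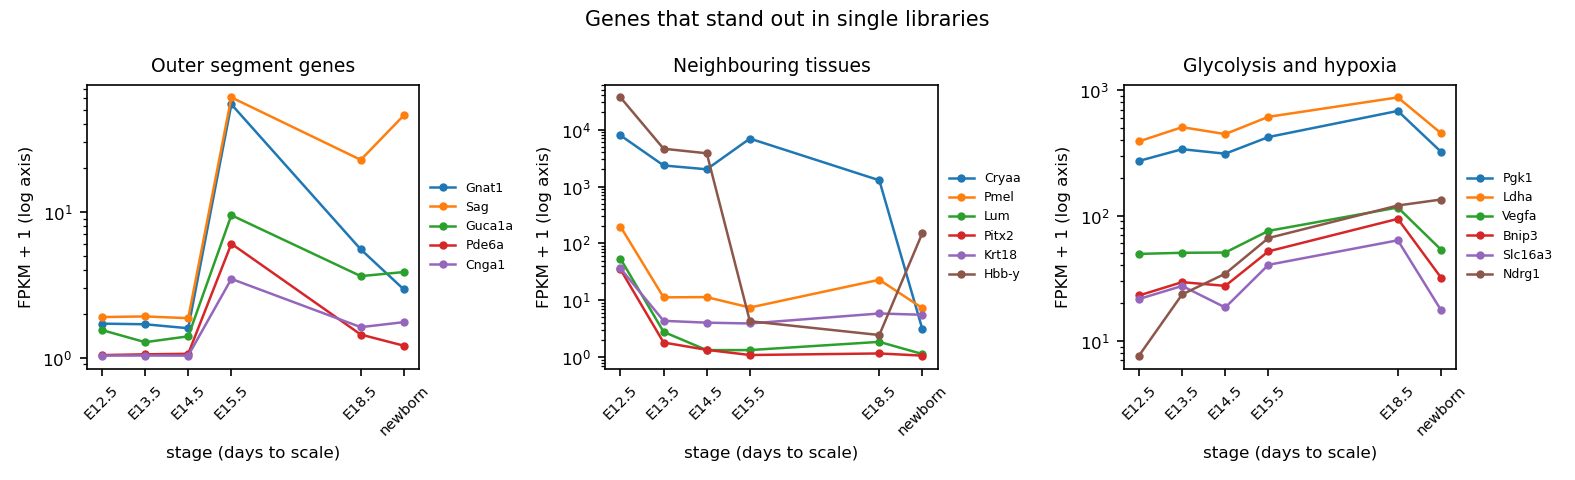
FPKM + 1 on a log axis against stage, days to scale, for outer segment genes, genes of neighbouring tissues and genes of glycolysis and hypoxia, with 1 point per library; the genes were picked for display after their values were seen. Gnat1 and Sag are highest at E15.5, Lum and Pmel at E12.5, and Pgk1 and Vegfa at E18.5.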

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

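No paired analysis was possible because each stage has 1 library. The only alternative added after seeing the data leaves out the E12.5 and E15.5 libraries together, and it kept the rising, falling and list counts within 1.5 times (1538, 1410 and 10). The trend counts also stayed within that range under both pseudocounts, both filters, quantile normalization, the later newborn age, stage order and eBayes without trend. With equal totals 3299 genes rose and 701 fell, against 1496 and 1377. Leaving out 1 library gave 0 to 1340 rising and 0 to 1216 falling genes, with 0 and 0 without the newborn, 202 and 177 without E18.5, 631 and 474 without E13.5, 813 and 680 without E14.5; the cause was not tested. Of the 89 named genes past the threshold, none reversed in the alternatives run for them, which were those above except the filters and the joint omission; without the newborn all 89 lost their call, without E18.5 64, without E13.5 43, without E14.5 27 and without E12.5 24. The 11 called lists became 0 with an estimated correlation and 2 with fry (amacrine and horizontal, ribosomal), and 8 to 14 when 1 library was left out. The count of 0 peaking genes became 3 with a pseudocount of 0.1, 27 at a mean of 5 FPKM, 23 with equal totals and 8 with quantile normalization, and the count of 0 dipping genes 3 at a mean of 5 FPKM and 1 with quantile normalization; the cause was not tested. It stayed at 0 with each library left out. The 2-fold counts follow the pseudocount and filter by construction. With a pseudocount of 5, 748 genes were higher and 601 lower in the newborn than at E12.5, and the 5 steps held 527, 92, 203, 187 and 143 genes in order of age; with a pseudocount of 0.1 the steps from E13.5 on held 320, 767, 577 and 385. At a mean of 5 FPKM, where fewer genes enter, 898 were higher and 604 lower over the series, and the steps from E12.5, E14.5, E15.5 and E18.5 held 676, 284, 236 and 151. Depth limits genes near 1 FPKM, where counting error alone is about 15% for a transcript of 2 kb.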

Other observations

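Of the tests given here, 3 were chosen only after the result was seen: the early photoreceptor regulators at E15.5, the mean filter on the late photoreceptor genes, and the stress genes at E18.5. Globin transcripts of embryonic and adult type both varied widely between the libraries. The embryonic beta-like globins Hbb-y and Hbb-bh1 stood at 36823 and 852.1 FPKM at E12.5, at 3839 and 41.9 at E14.5 and at 3.29 and 0.099 at E15.5, while the adult chains Hba-a1 and Hbb-b2 stood at 6283 and 554.8 FPKM at E12.5, 3141 and 798.1 at E14.5 and 811.9 and 274.8 at E15.5. All 4 were lowest at E18.5, at 1.45, 0, 155.5 and 30.5 FPKM, and the newborn library held more of them, with 1627 FPKM of Hba-a1 and 152.0 of Hbb-y. None passed the trend test. The close copies of these genes make the split between them uncertain.

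Some further genes had large step differences, although no gene passed the test of the second-order term in limma (1753 negative and 1025 positive at an unadjusted p under 0.05). Sst, which encodes somatostatin, stood at 5.02, 53.8, 34.7, 23.9, 2.42 and 0.48 FPKM from E12.5 to the newborn. Crabp1, a retinoic acid binding protein, stood at 250.5, 600.7, 312.4, 61.1, 102.1 and 140.4 FPKM. Prss56, a serine protease, was at 0.030 FPKM at E14.5, 28.1 at E18.5 and 9.40 in the newborn. These genes were chosen after their values were seen, and 1 library per stage gives no replicate check.

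Some outer segment genes, chosen after their values were seen, were high in the E15.5 library (Gnat1 53.6 and Sag 59.9 FPKM). In the rod list 7 of 19 members were highest at E15.5 and 12 in the newborn. Lens genes were high at E15.5 too, 18 of 18 at least 2-fold higher than at E14.5 and 17 of 18 at least 2-fold lower by E18.5. The erythroid median differed by -1.98 log2 from E14.5 to E15.5. The median shift over all genes was -0.0048 log2, so no shift common to all genes appears in the values. This does not decide on a scaling error. The authors' scaling is not known, and one that centres the median gene would leave no such shift in any case. An early start of the rod programme stays open: 6 of 6 regulators (Crx, Nrl, Nr2e3, Prdm1, Neurod1, Otx2) were higher at E15.5 than at E14.5, by 0.92 log2 at the median, but all 6 were also higher in each later step. RNA, or reads, of a more mature retina in that library is another candidate explanation that stays open. Of 11 late photoreceptor genes with a mean of at least 1 FPKM, 5 (45.5%) lay above both neighbouring libraries, against 21.4% of all genes. It was 9 of 15 among those reaching 1 FPKM anywhere, a choice that admits genes by the E15.5 value itself. The mean filter also admits some genes, such as Guca1b and Cngb1 of the 5, only through their E15.5 value. The most abundant of the 5, Reep6, stood at 7.27 FPKM but also at 6.42 at E12.5, Rdh12 at 4.41 against 1.04 and Guca1b at 3.86 against 1.70, and of 12 late inner retina genes, 4 of them seen before the list was made, 7 lay above both neighbours, with 2 of the 6 that reached 1 FPKM.

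Markers of neighbouring tissues were highest in the E12.5 library. The median gene shifted by 0.0696 log2 to E13.5, so no large shift common to all genes appears. Library scaling is not decided by this, since a scaling that centres the median gene would leave no such shift. Tissue carried along in the E12.5 dissection may explain these markers. A list of mesenchyme, pigment epithelium and surface epithelium genes was made before their values were seen. Of 22 members reaching 1 FPKM anywhere, 21 (95.5%) were highest at E12.5, and 10 of 11 with a mean of at least 1 FPKM, against 24.7% of all genes. The median of the 22 stood at 4.55 FPKM at E12.5 and 0.354 at E13.5. All 22 reached 1 FPKM at E12.5 and 6 at E13.5, so this choice admits genes by the E12.5 value itself, as a mean filter also can. The most abundant were Col5a1 at 27.1, Prrx2 at 12.97, Col6a1 at 12.9 and Col6a2 at 12.8 FPKM, of which Col6a1 was higher in the newborn (31.0 FPKM), and 5 of the 22 still reached 1 FPKM there. The libraries were made from dissected retinas, so such cells elsewhere in the eye would appear only as tissue carried along. A true fall of such cells within the dissected retina between these days stays open. The cause of the lens signal, which was highest at E15.5 and near 0 in the newborn, was not tested.

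Glycolysis and hypoxia response genes were highest in the E18.5 library, 18 of 22 and 14 of 17, against 13.9% of all genes. The median shift to the newborn was 0.011 log2, so no large shift common to all genes appears. It does not decide on library scaling, for a scaling that centres the median gene would leave no such shift. Handling stress stays open: 1 of 12 stress and immediate early genes reaching 1 FPKM (8.3%) was highest at E18.5, but the list's median was 0.11 log2 higher than at E15.5 (percentile 88.8 of random lists). A coordinated low oxygen response is consistent with a further list made before its values were seen: 12 of 20 hypoxia target genes (60.0%) were highest at E18.5, and 11 of 18 with a mean of at least 1 FPKM, among them Fam162a (128.4 against 65.1 FPKM in the newborn), Ak4 (8.99 against 2.24) and Plod2 (23.8 against 13.3). Others of the 12 differed little from the newborn, such as Insig2 (15.1 against 14.3) and Selenbp1 (1.22 against 1.05). Of the remaining target genes 3 were highest at E12.5, 3 at E13.5 and 2 in the newborn. Whether such a response arose in the womb, from the change of oxygen at birth, or between death and lysis of the tissue was not tested. From E18.5 to the newborn the lens and erythroid lists differed too, by -7.41 and 3.08 log2.

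Chance was tested by giving the 6 libraries other orders of age. Of the 100 orders used, 1, the real one, gave as many as 2873 genes with a linear trend. The highest of the others gave 1667, with E12.5 and E13.5 exchanged. Chance order is thus unlikely for that count, but differences between libraries that run with age are not excluded by it. For the curvature count of 0 all orders, 100 of 100, give as many by construction, which says nothing about chance. The highest other order gave 2256 genes. It has E13.5 and E12.5 in its middle, E15.5 and E14.5 next to them, and the newborn and E18.5 at its ends. Libraries of like age thus stand opposite each other around the middle, and whether this gave the count was not tested.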
